A study of Drosophila melanogaster with 47 samples.

How the data were processed

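Chromatin immunoprecipitation and sequencing data were analysed for 14 regulators in 16 groups of Drosophila embryos, larvae, adult females and cell lines. Per the labels' protocols, sonicated chromatin was precipitated with an antibody, libraries were made by tagmentation and sequencing was done on an Illumina instrument. The submitters' processing notes name CASAVA 1.7.0, BWA, MACS2 and the genome build dm3; the order, settings, thresholds and control samples of each step are not given in the sources used here. The labels name 1 list for all immunoprecipitated replicates of a group. Whether reads were pooled before peak calling is not stated, so replicates could not be compared, and the labels do not say whether they came from separate cultures or animals.

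Each deposited list gave the position of a peak, the authors' fold enrichment over background as a linear ratio, the authors' −log10 p, and the offset of the summit from the peak start in bp, another deposited value. The fold and the score of a peak are the authors' own and were used to describe, rank or filter peaks within 1 list. Between lists, only the lowest −log10 p of each list was compared. Peak names in the lists carried ranks. The highest rank exceeded the number of lines by 6 for Cmi, 5 for Notch, 4 for CG8478 and 1 for Lola, and the ranks without a line were not analysed here. The labels hold 1 input for the 4 Kc167 lists and 1 for the prd lists, so shared controls may add to overlap there. Read depth per sample is unknown, so no list was corrected for it, and list length was not read as the extent of binding.

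Positions were written 1-based. Of the 12745 peaks, 12462 on the arms 2L, 2R, 3L, 3R, 4 and X entered the comparisons. The span of an arm was taken from the outermost peaks of all lists. Peaks were called shared at an overlap of at least 1 bp. For each of the 120 pairs, the number of peaks of the shorter list that overlapped the longer was set against 10000 circular shifts within each arm (one-sided permutation test), made by moving the shorter list, which gives the same relative placement as moving the longer one, and the ratio of observed to expected was given as log2 after adding 0.5 to each. Intervals of log2 ratios and of their differences are 95% percentile intervals from 1000 resamples of 1 Mb blocks, with the expected number held at its mean over the shifts. Shares have exact Clopper-Pearson intervals, which cover counting error only; p-values do not measure spread between replicates, and a count of 0 was given the limit of 3 counts of the total.

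Material and antibody labels were permuted 100000 times over the 16 lists, with the mean log2 ratio within classes minus that of other pairs as the statistic (two-sided). Peaks of all lists were merged at 1 bp overlap, the lists of 1 regulator counted once, and the number of regions with 5 or more regulators was compared with 1000 sets of shifts of all lists. Scores of shared and private peaks were compared by a two-sided permutation test of the median percentile (100000 permutations), and the share of peaks on X by Fisher's exact test against the merged regions without a peak of the list. Adjusted values are Benjamini-Hochberg. These tests, their alternatives and the rule for named regions were fixed before the data were examined. The rule names the 3 peaks with the highest score in each list and the 10 merged regions with the most regulators, with ties broken by width and then position. The comparisons of partners of the prd, Hr78, Notch and insv peaks, the shares on arm 4 and the intervals from resampled blocks were added after the data were seen. Tests of gene lists and of sequence motifs at peaks had also been planned and were not run, since no genome or annotation of dm3 was used here. A table of gene names of a later assembly served only to check the regulators' names.

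The overlap test was checked on simulated lists, 100 per setting with 2000 shifts each. Lists placed at random by shifts gave p under 0.05 in 3% of draws for the Hr78 pair (688 and 1249 peaks), 1% for the prd pair (130 and 348 peaks) and 8% for Su(H) and Notch (2016 and 2448 peaks). With 5% of peaks planted on the other list, all 100 draws passed in each pair, and the excess over expectation came out at 4.90%, 4.65% and 4.88%.

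Alternatives were a 50% overlap of the shorter peak, a distance of up to 500 bp, the top-scoring 50% of each list, random placement of single peaks, Fisher's exact test over merged regions, equal list lengths, regions with 5 or more regulators left out, the Jaccard index of covered bases, each list left out in turn, other numbers of regulators, peaks of 400 bp around the centre and the 250 best peaks of each list. Summits within 250 bp, and 2000 bp for the prd lists, were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.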

Results

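Binding of 14 transcriptional regulators was mapped in Drosophila melanogaster by chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is recovered with an antibody and sequenced. The 47 samples comprised 35 immunoprecipitated samples and 12 input samples of chromatin not enriched with an antibody. The immunoprecipitated samples formed 16 groups, 13 with 2 replicates and 3 with 3 replicates, and each group had 1 peak list. The material was embryos for 6 lists, larvae (stage label W3L) for 4, Kc167 cells for 4, S2 cells for 1 and adult females for 1. Kc167 and S2 are established cell lines of embryonic origin. Anti-GFP antibody against a tagged regulator was used for 6 lists (Stat92E, Notch, Lola, AbdB and Hr78 at 2 stages), and antibodies raised against the regulators themselves were used for the other 10. Read depth per sample was unknown, and the lists carried no value per replicate, so the intervals on shares of peaks cover counting error only.

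The regulators differed widely in the number of regions at which binding was called. Notch, the receptor whose intracellular domain acts in the nucleus, had the most peaks, 2516 in larvae. Its DNA-binding partner Su(H) had 2018 peaks in Kc167 cells, and Cmi (Cara Mitad), a subunit of a histone methyltransferase coactivator complex, had 1685 in embryos of 0 to 8 h. The uncharacterised regulator CG8478 had 1343 peaks in S2 cells, and the nuclear receptor Hr78 had 1288 in larvae and 731 in embryos of 8 to 16 h. The Hox protein AbdB had 737 peaks, cnc, the fly relative of the stress regulator Nrf2, had 491 in adult females, and the ecdysone-responsive zinc finger protein br had 381. The shortest lists were those of the pair-rule protein prd (353 with antibody RF12 and 132 with RF13), the zinc finger protein Lola (330), the corepressor insv (218), the pair-rule repressor h (216), Stat92E of the JAK-STAT pathway (206) and dm, the fly Myc protein (100). Median peak widths lay between 158.5 bp for Lola and 411 bp for Cmi. The authors' lowest −log10 p in a list ranged from 2.62 for Su(H) to 7.64 for dm, so a longer list does not show that a regulator bound more regions.

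Most of the AbdB, Hr78, insv and h peaks lay where another regulator was also called, and the lowest shares were those of cnc, prd and br. The share of peaks overlapping a list of another regulator by at least 1 bp was 96.1% for AbdB (95% Clopper-Pearson interval 94.4 to 97.4), 91.8% for Hr78 in larvae (90.2 to 93.3), 89.5% for Hr78 in embryos (87.0 to 91.7), 84.8% for insv (79.3 to 89.3) and 81.8% for h (75.9 to 86.8). It was 33.1% for cnc (28.9 to 37.4), 39.1% for prd with RF12 (33.9 to 44.4), 41.8% for br (36.8 to 47.1) and 45.4% for prd with RF13 (36.6 to 54.4). Notch and Su(H), with the longest lists, stood between at 66.6% and 55.0%.

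**Figure D1:**
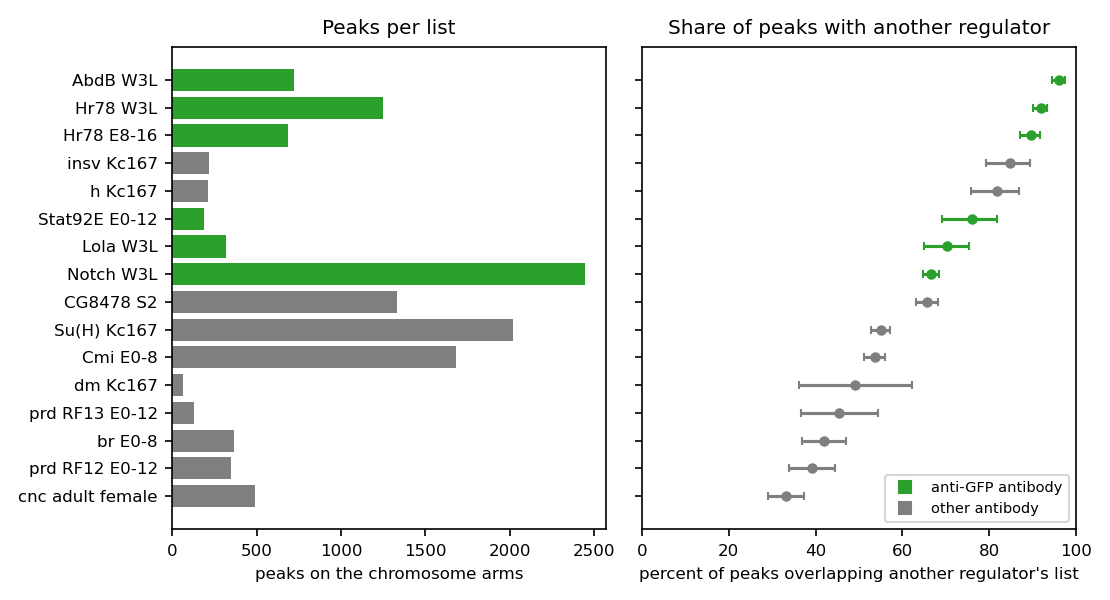
Peaks on the chromosome arms per list (left, bars) and percent of those peaks that overlap a list of another regulator (right, points with 95% Clopper-Pearson intervals), in the same order of lists. AbdB stands highest at 96.1% and cnc lowest at 33.1%.

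In most pairs of lists, across tissues and stages, regulators shared far more binding regions than lists shifted along the chromosome arms did. Of the 120 pairs, 108 had more shared peaks than 10000 circular shifts of 1 list against the other gave (one-sided permutation test, Benjamini-Hochberg adjusted p under 0.05 over the 120 pairs), and 94 of them reached 1e-04, the smallest p the shifts can give. The median pair had a log2 ratio of observed to expected shared peaks of 3.81. All 12 pairs that did not pass included a dm or prd list, and none of them shared more than 3 peaks. The shifts place peaks anywhere along an arm, so they do not allow for sequence that many lists favour. Among merged regions that at least 1 other list held, 79 of the 120 pairs passed (Fisher's exact test, adjusted p under 0.05). By log2 ratio after adding 0.5 to each count, Stat92E and Hr78 in embryos were the closest pair (6.34, 95% interval 5.98 to 6.61). They shared 103 of 187 Stat92E peaks. The Hr78 lists of both stages (6.25) and AbdB with Hr78 in larvae (6.16) followed. This order depended on the measure. Without the added 0.5, h and insv had the highest ratio, 142.4 against 132.8 for Stat92E and Hr78 in embryos. With summits within 250 bp, the Hr78 stages stood above Stat92E and Hr78 in embryos (log2 ratio 6.70 against 6.44).

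**Figure D2:**
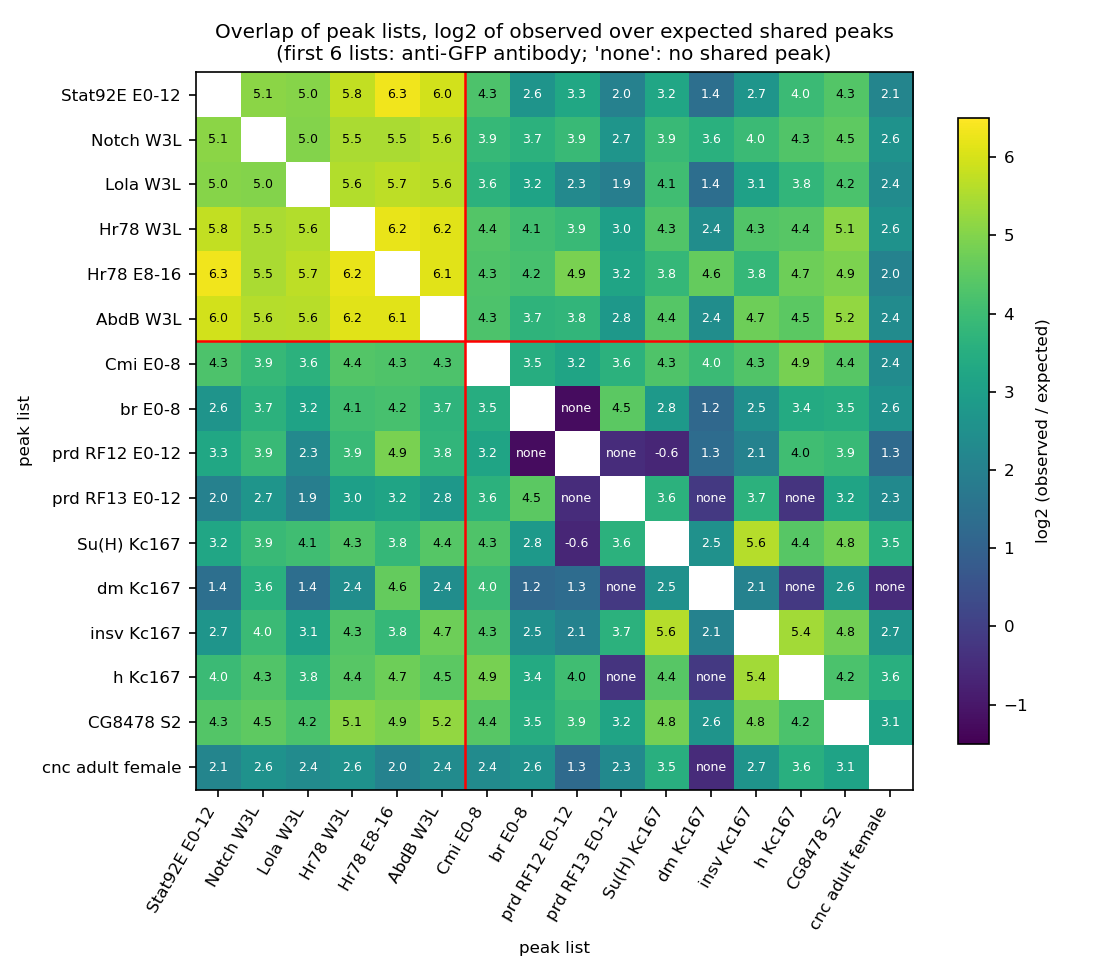
Log2 of observed over expected shared peaks for each pair of lists, with colour and number giving the same value. The first 6 rows and columns, inside the red lines, are the anti-GFP lists, whose pairs of different regulators lie between 5.03 and 6.34; pairs marked none shared no peak.

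On average, pairs of lists made with the anti-GFP antibody resembled one another more than other pairs did, across regulators and stages. Single pairs did not all follow, since insv and Su(H) reached a log2 ratio of 5.60 and Lola and Notch, both anti-GFP, 5.03. AbdB shared 90.9% of its 722 peaks with Notch (88.5 to 92.9), Hr78 shared 84.5% in larvae and 83.6% in embryos, Stat92E shared 63.6% and Lola 51.3%. The mean log2 ratio was 5.68 over the 15 pairs of anti-GFP lists and 3.24 over the other 105 pairs, a difference of 2.44 (permutation of the antibody labels over the 16 lists, 100000 permutations, two-sided p = 1.1e-04). Lists from the same material did not resemble one another detectably more than lists from different material, with a mean log2 ratio of 3.75 over 27 pairs against 3.48 over 93 pairs (permutation of the material labels, two-sided p = 0.444). All 4 larval lists and no cell line list were made with the anti-GFP antibody, and within embryos the single anti-GFP pair lay 3.36 above the other pairs, in a design whose exact permutation test of 15 arrangements cannot go below p = 0.0667 (exact two-sided p = 0.2).

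Relative to chance, Su(H) shared most with insv, a corepressor known to act with it, and shared less with Notch than with larval AbdB or Hr78. By share of Su(H) peaks the order was another, with Notch at 26.3%, Cmi and CG8478 at 25.1% each, larval Hr78 at 16.3%, AbdB at 11.2%, insv at 6.94% and Lola at 2.63%. In Kc167 cells 145 of 217 insv peaks overlapped a Su(H) peak (66.8%, 60.1 to 73.0), at a log2 ratio of 5.60. Notch in larvae and Su(H) in Kc167 cells shared 531 of the 2016 Su(H) peaks (26.3%, 24.4 to 28.3) and 453 of the 2448 Notch peaks (18.5%, 17.0 to 20.1), against 34.7 expected (log2 ratio 3.92, one-sided permutation p = 1e-04, the smallest possible). The Su(H) log2 ratio with Notch was lower than with AbdB (difference −0.49, 95% interval −0.67 to −0.30 from resampled 1 Mb blocks). It was also lower than with Hr78 in larvae (difference −0.41, −0.63 to −0.17). It did not differ detectably from that with Lola (difference −0.14, −0.52 to 0.35), and it was 1.68 below that with insv (1.42 to 1.91). The Notch list (2448 peaks) was longer than those of larval Hr78 (1249), AbdB (722), Lola (316) and insv (217). It was not cut to their lengths, so these differences cannot be told apart from list length. Notch peaks that no other anti-GFP list held overlapped Su(H) less often than those that at least 1 of the other 5 held, 12.4% of 1175 against 24.1% of 1273 (Fisher's exact test, p = 6.58e-14, adjusted 1.32e-13 over 4 lists tested). The same held for the other 3 lists tested, with Cmi at 13.3% against 23.6%, CG8478 at 10.2% against 29.7% and insv at 1.11% against 3.85%, so the difference was not particular to Su(H). The Notch peaks held by other anti-GFP lists were also the wider ones (median 568 against 265 bp), which gives them more chance to overlap. The lists came from different material and antibodies, which cannot be separated from the pathway.

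By log2 ratio, h, a further repressor in Kc167 cells, shared most with insv and Cmi. Without the 0.5 added to each count, lists including Stat92E (ratio 56.2) stood above Cmi (35.5). Of the 209 h peaks, 29 overlapped insv (13.9%, log2 ratio 5.39) and 76 overlapped Cmi of embryos (36.4%, log2 ratio 4.86), while by share Notch with 35.9% and Su(H) with 25.8% stood above insv. The insv peaks with Su(H) also had CG8478 more often than those without, 35.9% of 145 against 12.5% of 72 (Fisher's exact test, p = 2.22e-04, adjusted 6.66e-04 over 3 lists). Notch was found at 33.8% and 19.4% of them (Fisher's exact test, adjusted p = 0.0576), and h at 11.0% and 16.7% (adjusted p = 0.284). CG8478 in S2 cells shared 35.4% of its 1333 peaks with Su(H), and AbdB shared 34.8% of its peaks with CG8478, at log2 ratios of 4.83 and 5.22. The labels hold 1 input for Kc167 cells, and the peak lists alone do not separate overlap among Su(H), insv, h and dm from effects of a shared input.

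Hr78 was called at many of the same regions in embryos of 8 to 16 h and in larvae. Of 688 embryonic peaks, 495 overlapped a larval peak (71.9%, 68.4 to 75.3), and 503 of 1249 larval peaks overlapped an embryonic one (40.3%, 37.5 to 43.1), against 6.03 expected (log2 ratio 6.25, one-sided permutation p = 1e-04, the smallest possible). With the larval list cut to its 688 best peaks 409 peaks were shared (59.4%). In the full lists the shared peaks were nearly as many in embryos as in larvae (495 and 503). The unequal shares therefore reflect the lengths of the lists, 688 and 1249 peaks. The overlap of the stages was higher than that of embryonic Hr78 with Notch (difference in log2 ratio 0.77, 0.66 to 0.89). It was not detectably different from the overlap of embryonic Hr78 with larval AbdB (difference 0.10, −0.16 to 0.40) or with embryonic Stat92E (difference −0.10, −0.37 to 0.27). By share of embryonic Hr78 peaks, the longer Notch list stood above larval Hr78, at 83.6% against 71.9%. Larval peaks also present in embryos held Stat92E in 18.1% of 503 cases and larval-only peaks in 0.938% of 746 (Fisher's exact test, p = 3.67e-30, adjusted 1.03e-28 over 28 tests). Of the 28 tests 17 passed. All of these had the higher share at stage-shared peaks, except Su(H) among larval peaks and dm among embryonic ones. Among embryonic peaks AbdB was found at 46.7% against 10.4% and Notch at 94.1% against 56.5%. Among larval peaks h was found at 6.16% against 1.61%. The difference was therefore not particular to Stat92E. Su(H) went the other way among larval peaks, with 17.7% of the stage-shared and 28.6% of the larval-only peaks (Fisher's exact test, adjusted p = 3.47e-05), but not among embryonic ones, with 17.6% of the stage-shared and 13.0% of the embryo-only peaks (adjusted p = 0.247). Embryo-only peaks overlapped dm more often than stage-shared peaks, 6.74% of 193 against 1.01% of 495 (Fisher's exact test, adjusted p = 2.38e-04), whereas among larval peaks dm was found at 5 of 503 stage-shared and 0 of 746 larval-only ones (adjusted p = 0.0172). Stage-shared peaks were the wider ones, with a median of 399 against 280 bp in larvae and 334 against 183 bp in embryos.

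The antibodies RF12 and RF13 against prd gave no common peak in embryos of 0 to 12 h. None of the 130 RF13 peaks on the arms overlapped any of the 348 RF12 peaks, which allows a share of up to 2.31% (3 counts of the total), and 0.203 were expected by chance (one-sided permutation p = 1). With a distance of up to 500 bp allowed, 3 RF13 peaks had an RF12 peak nearby (log2 ratio 1.74, permutation p = 0.026). The lists also differed in their partners at 7 of the 14 other lists (Fisher's exact tests, adjusted over 14). RF13 peaks overlapped Su(H) in 18.5% of cases and br in 13.1%, against 0.575% and 0% for RF12 (Fisher's exact test, adjusted p = 1.37e-11 and 7.62e-10). Within 500 bp RF12 had a Su(H) peak at 15 peaks (4.31%), and its log2 ratio with Su(H) turned from −0.64 to 0.98 (permutation test, adjusted p = 0.0104). RF12 peaks overlapped Notch in 24.1% and embryonic Hr78 in 14.4% of cases, against 12.3% and 6.15% for RF13 (Fisher's exact test, adjusted p = 0.0181 and 0.0474).

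Regions bound by many regulators were far more frequent than independent placement anywhere along the arms gives. Merging all peaks on the arms gave 6511 regions, of which 4212 held 1 regulator and 333 (5.11%) held 5 or more of the 14, against a mean of 0.014 and a highest value of 1 in 1000 sets of shifted lists (one-sided permutation p = 0.001, the smallest possible). Notch was present in 94.9% of the 333 regions, Hr78 of larvae in 85.3%, CG8478 in 78.4%, AbdB in 75.1%, Cmi in 66.1% and Su(H) in 63.4%. The lowest shares were those of cnc (6.91%), prd with RF13 (4.8%) and dm (2.10%). By share of a list's own regions the order was another, with Stat92E at 37.0%, AbdB at 36.3%, Notch at 13.3% and Su(H) at 11.6%. Without the Notch list the number of regions with 5 or more regulators fell to 155, without CG8478 to 198 and without AbdB to 215. The 250 best peaks of each list gave 46. Regions with 5 or more regulators had a median width of 1056 bp, against 253 bp for regions with 1. Merging joins peaks in a chain, so the peaks of 1 region need not all overlap one another.

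**Figure D3:**
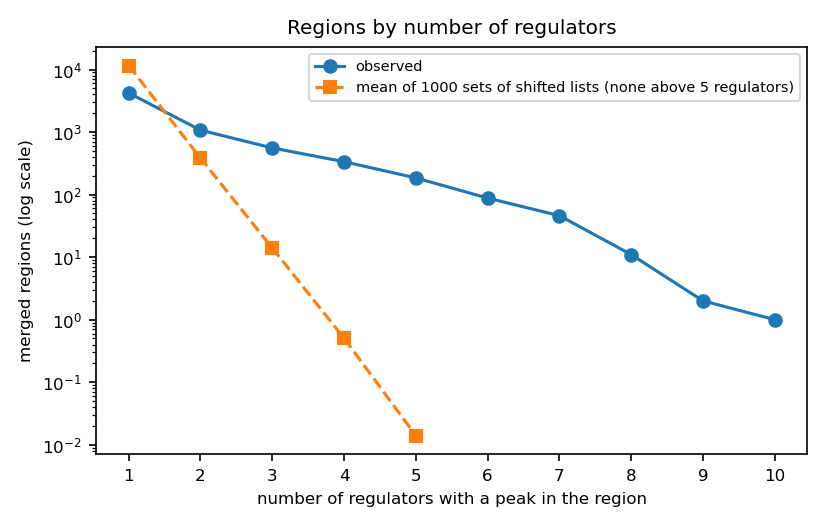
Number of merged regions (log axis) by the number of regulators with a peak in them, as observed (circles) and as the mean of 1000 sets of circularly shifted lists (squares). The observed line runs from 4212 regions with 1 regulator to 1 region with 10, and no shifted set had a region with more than 5.

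The region with the most regulators lay on 3R at 25597264 to 25599811 (build dm3, here and throughout) and held 10: Su(H), Notch, Lola, insv, Hr78 of larvae, h, Cmi, CG8478, br and cnc. Regions with 9 regulators lay on X at 12628469 to 12630622 and on 3R at 16654547 to 16656273. The other 7 regions named by the rule held 8 regulators each. They lay on 2L at 11806132 to 11809369 and at 2196462 to 2198368, on X at 2015385 to 2018176, on 2R at 6317066 to 6319252, 11990139 to 11992213 and 18157711 to 18159330, and on 3L at 16044793 to 16046546. All 10 regions held Notch, Hr78 of larvae, Cmi and CG8478, and 9 of them held Su(H). Genes at these positions were not determined, since no annotation of this build was used here.

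**Figure D4:**
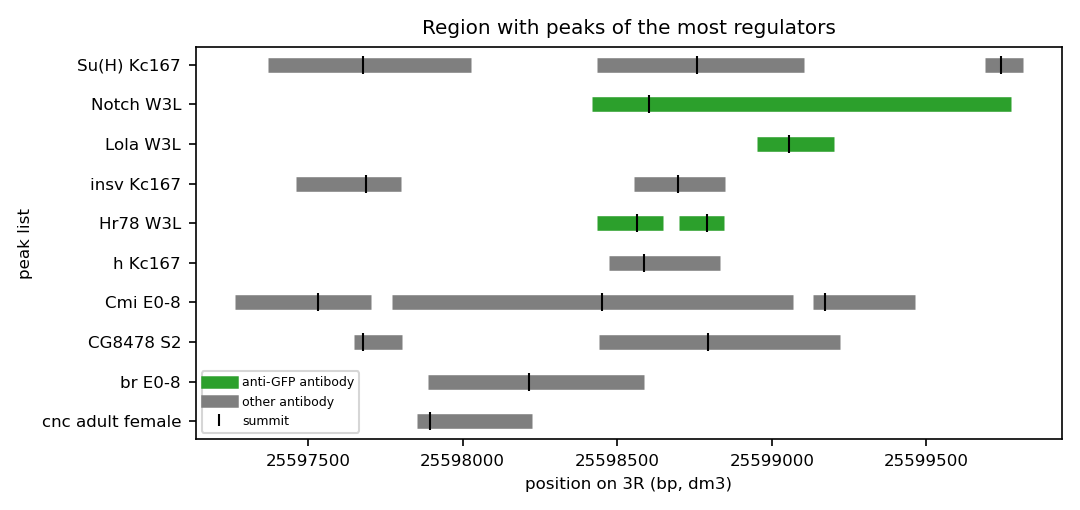
Map of the region on 3R with the most regulators, with each bar a peak of the named list (green for the anti-GFP antibody, grey for other antibodies) and each tick its summit. Peaks of 10 lists lie between 25597264 and 25599811, with summits from 25597532 (Cmi) to 25599740 (Su(H)). Not all of them overlap one another, as the cnc peak (25597854 to 25598226) and the Lola peak (25598951 to 25599201) show.

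Shared peaks had the higher scores in most lists. In 11 of the 16 lists, peaks overlapping another regulator had higher scores (the authors' −log10 p, as a percentile within the list) than private ones (two-sided permutation tests of the median, 100000 permutations, adjusted p under 0.05 over 16 lists). The difference in median percentile was 33.5 for Notch, 31.6 for Hr78 in larvae, 26.0 for Hr78 in embryos and 15.3 for Su(H), with adjusted p of 3.2e-05, 3.2e-05, 8e-05 and 3.2e-05. In the lists of insv, br and prd with RF12 the median of shared peaks was the lower, by differences of −12.4, −3.80 and −7.18 percentiles (permutation test, adjusted p = 0.232, 0.482 and 0.164). In all 11 lists that passed, shared peaks were also wider, and a wider peak has more chance to overlap. The medians were 508 against 253 bp for private ones in Notch, 354 against 237.5 bp in Su(H) and 381 against 189 bp in AbdB. Median fold was higher for shared peaks in all 11, but by little in some. It was 2.43 against 2.41 in AbdB and 2.89 against 2.66 in larval Hr78.

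Binding of dm, among the peaks on the arms, was found unusually often on the X chromosome. Of 61 dm peaks on the arms, 30 were on X (49.2%, 36.1 to 62.3), against 20.7% of the regions without a dm peak (Fisher's exact test, two-sided, adjusted p = 2.15e-05 over 16 lists). The insv list had 30.9% on X against 20.6% (Fisher's exact test, adjusted p = 0.00249) and prd with RF13 had 30.8% against 20.7% (adjusted p = 0.0273), which in the top-scoring 50% of each list was 33.8% and no longer passed (adjusted p = 0.0643). Lola with 13.9% against 21.3% and prd with RF12 with 12.6% against 21.4% had fewer (Fisher's exact test, adjusted p = 0.0055 and 4.7e-04). The other 11 lists had between 17.7% and 23.3% on X and did not pass the test.

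**Figure D5:**
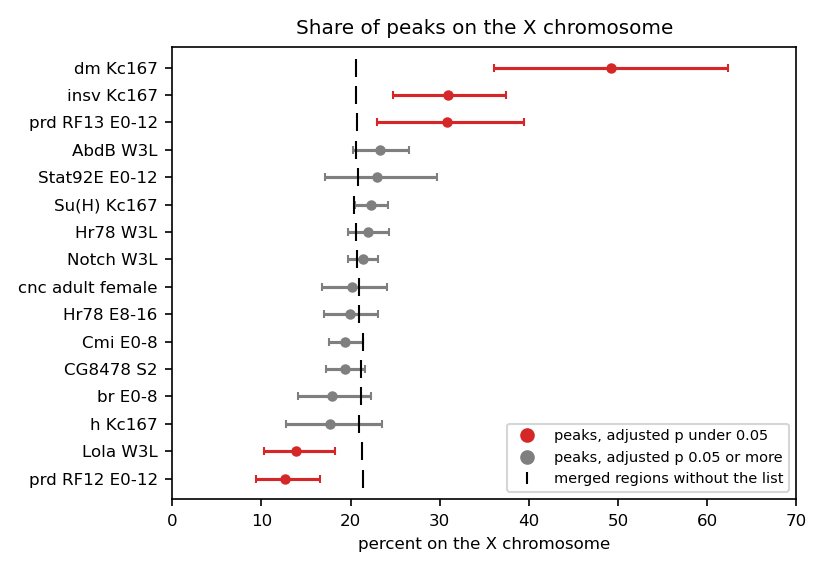
Percent of each list's peaks on the arms that lie on the X chromosome (points with 95% Clopper-Pearson intervals, red where the adjusted p is under 0.05), with ticks for the merged regions without a peak of the list. The dm list stands highest at 49.2% and prd with RF12 lowest at 12.6%.

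Among the 48 peaks with the highest scores, 3 from each list, 44 overlapped a peak of another list and 14 overlapped 5 or more other lists. The highest peaks of Notch (2R, 15993649 to 15994371, 7.07-fold enrichment), AbdB (2R, 15993792 to 15994329, 5.24-fold) and Stat92E (2R, 15993920 to 15994318, 2.64-fold) were the same region, which was also the third of Hr78 in embryos. The highest Su(H) peak (3R, 16608141 to 16609068, 3.71-fold) overlapped insv, Notch, AbdB and larval Hr78, and the other 2 of its named peaks also overlapped insv. The highest h peak (2R, 17590618 to 17591214, 3.78-fold) overlapped insv and Cmi, and the second h peak (3R, 25541644 to 25543515) was the third of Cmi. The highest cnc peak lay on 2L at 16525853 to 16526779 (5.00-fold). The 3 highest RF12 peaks, on 2R at 12687629 to 12687902 and on X at 17645581 to 17646020 and 5507087 to 5507363, overlapped no other list, and neither did the second CG8478 peak, on 3L at 17995665 to 17996604. The 3 highest dm peaks lay on the mitochondrial genome, and the 3 highest br peaks on unplaced sequence (Uextra).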

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

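All tests of explanations in this part were chosen after the results were seen, except the comparison of odds ratios between antibody classes.

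Peaks outside the 6 arms, which the overlap, region, score and X share tests of the report did not use, numbered more than the 3 that a count of 0 allows in 12 lists. There were 68 for Notch, 43 for Hr78 in embryos, 39 for Hr78 in larvae, 39 for dm, 19 for Stat92E, 15 for AbdB, 14 for Lola, 13 for br, 10 for CG8478, 7 for h, 5 for Cmi and 5 for prd with RF12. In the anti-GFP lists most of them lay on assembled heterochromatin, 54 of 68 for Notch and 38 of 39 for Hr78 in larvae.

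The extent of sharing differed between the 2 prd lists for 7 other lists. RF12 minus RF13, in percentage points of peaks shared, was −17.9 for Su(H), −13.1 for br, −8.12 for Cmi, −5.29 for insv, 3.74 for h, 8.22 for embryonic Hr78 and 11.8 for Notch.

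The anti-GFP lists shared regions across regulators and stages. Regions bound in most materials predict that pairs of anti-GFP lists stand out no more than other pairs among regions that another list holds. Their mean log2 odds ratio there was 2.94 higher (4.15 against 1.21, permutation p = 1.1e-04). The other list could be a further anti-GFP list, and 1 was enough. The comparison therefore does not decide whether regions bound in most materials are the cause. Regions recovered by the antibody or the tag predict that embryonic anti-GFP lists resemble larval anti-GFP lists of other regulators more than embryonic lists of other antibodies, and the mean log2 ratio was 2.03 higher (exact permutation test of 70 arrangements, one-sided p = 0.0143, the smallest possible). That difference restates the pattern, and joint binding of the tagged regulators would give it too. The antibody or tag alone also predicted that regions of 2 or more tagged regulators overlap lists of other antibodies no more than by chance. That part of the prediction was not met. Of the 1266 such regions 697 overlapped a list of another antibody, against 52.3 expected (log2 ratio 3.72, permutation p = 1e-04, the smallest possible). Joint binding would give this overlap, and so would sequence that many lists favour, which the shifts do not allow for. Of the 60 pairs of an anti-GFP list and another list, 58 had already passed against such shifts. The overlap could thus be foreseen and does not count against the antibody or tag. A part played by the antibody or tag cannot be told apart from joint binding, since no anti-GFP list from untagged animals was analysed here.

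The prd lists shared no peak although both name the same protein and stage. At these list lengths simulated sharing of 5% of peaks was detected in all 100 draws, so the overlap test was not too weak for sharing of that extent. Whether the lists were too short to hold the same sites stays open, since of the 5 lists of other regulators with no more peaks on the arms than RF12, 3 overlapped an RF13 peak (8 for insv, 2 for Stat92E and 2 for Lola) and those of dm and h overlapped 0. Peaks displaced by up to 2000 bp would have met at 10% or more of RF13 peaks, and 2.31% did (0.479 to 6.60). The lists differed in sharing with 7 of the 14 others, which background in the list of 1 antibody, recognition of different forms of the protein and a list that holds another sample would all give, so these cannot be told apart.

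The dm list held 37 of its 100 peaks on mitochondrial or unplaced sequence (27.6% to 47.2%), including its 3 highest. Lists from other material held such peaks at lower shares. Hr78 in embryos had 4 mitochondrial and 10 unplaced of 731, CG8478 3 and 5 of 1343, and br 10 unplaced of 381, including its 3 highest. Each of the 3 highest dm peaks overlapped a peak of CG8478 or of embryonic Hr78. A high copy number of these sequences in Kc167 cells would put such peaks in the other 3 Kc167 lists too, but 0 of their 2452 peaks lay there (limit 0.122% by 3 counts of the total, upper Clopper-Pearson limit 0.15%), although those lists reach lower scores. Few strong dm sites on the arms stay open, since the median −log10 p was lower on the arms than off them (difference −2.05, 9.43 against 11.5, permutation p = 0.0205) but the median fold was higher (3.77 against 3.56). No other explanation was tested for this pattern.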

How the results depend on the processing

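Summits within 250 bp, 2000 bp, the prd, Hr78 and Notch peak alternatives, those of the shares of peaks shared and the removal of peaks of other anti-GFP lists were chosen after seeing the data. The number of pairs sharing more than chance was 101 to 109 under 5 of the 6 other settings and 79 with Fisher's exact test over merged regions, against 108. Of the 60 pairs of an anti-GFP list and another list, 58 passed, and 39 did once peaks shared among the anti-GFP lists were left out, which shortens those lists. The Hr78 and Su(H)-Notch overlaps passed under all 5 settings tried for each. The log2 ratio of the prd lists turned from −0.49 to 1.74 within 500 bp (permutation p = 0.026) and 0.75 within 2000 bp (permutation p = 0.225). Both rested on 3 RF13 peaks, and the cause was not tested. With 0 shared peaks against 0.203 expected, the value of −0.49 does not show overlap below chance. RF12 and Su(H) likewise turned from a log2 ratio of −0.64 to 0.98 within 500 bp, with 15 RF12 peaks. The antibody difference stayed between 2.22 and 2.67 with each list left out and kept its call; among embryo pairs only it was 3.36 and lost it, since 15 arrangements are too few. The material difference ran from 0.05 to 0.58 and never passed. Regions with many regulators numbered 669 at 4 or more and 60 at 7 or more, 46 from the 250 best peaks, and 155 to 332 with each list left out, the lowest without Notch (155), CG8478 (198) and AbdB (215). Counts of lists passing the score, X share, prd, Hr78 and Notch peak tests stayed within 1.5 times. The X share of prd with RF13 lost its call in the top-scoring 50% of each list (33.8%, Fisher's exact test, adjusted p = 0.0643), and within 500 bp the score difference lost it for dm (24.6) and RF13 (14.2). With summits within 250 bp the score differences of Lola (13.3) and insv (−16.8) passed. Within 500 bp or at 50% overlap, 13 of 32 shares of peaks shared with another regulator left their intervals, and within 500 bp the shares of br (51.1%), dm (55.7%) and prd with RF13 (55.4%) rose above 50%. Alternatives for genes and motifs at peaks were not run.

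No paired analysis was possible because each group had 1 peak list and no values per replicate, and leaving out replicates was not possible for the same reason. Depth is unknown and limits which peaks each list held.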

Other observations

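The tests on arm 4 were chosen after the data were seen. Several regulators were found unusually often on chromosome 4, a small chromosome rich in heterochromatin. Hr78 in embryos had 41 of 688 peaks there (5.96%, 4.31 to 8.00), h had 5.26%, Lola 4.75%, Stat92E 3.74%, Hr78 in larvae 3.60% and Notch 2.61%, against 0.605% to 1.28% of the regions without each list (Fisher's exact tests, adjusted p between 3.33e-16 and 0.0227 over 16 lists). Su(H) with 0.298%, Cmi with 0.595%, CG8478 with 0.525% and cnc with 0.204% had fewer than the regions without them (Fisher's exact tests, adjusted p = 4.79e-07, 0.00407, 0.00572 and 0.0339). All the lists with more, except h, were made with the anti-GFP antibody and share many peaks, so they are not independent. Their regions also enter the background of the lists with fewer. AbdB, made with the same antibody as Hr78, had 0.693% (Fisher's exact test, adjusted p = 0.164). In the top-scoring 50% of each list, 7 lists passed this test, against 10 with all peaks.

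The 283 peaks off the arms merged into 134 regions, of which 50 held more than 1 regulator and 58 held anti-GFP lists alone. The region with the most regulators lay on 2RHet at 197542 to 198952 and held 7, with all 6 anti-GFP lists, br and prd with RF13. A region on 2RHet at 471447 to 472321 and one on 3LHet at 1396047 to 1397217 each held all 6 anti-GFP lists and h. The highest br peak (Uextra, 19603907 to 19604047, 8.99-fold) overlapped the second of embryonic Hr78 and a Notch peak.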
